A study of Homo sapiens with 6 samples.

How the data were processed

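Gene expression was measured by RNA sequencing in 6 libraries from 786-O cells, 3 labelled sgControl and 3 labelled sgPLOD2. Per the labels' protocols, RNA was taken with Trizol and libraries were made with a standard Illumina protocol. CASAVA, HISAT2 2.1.0, StringTie 1.3.4 and the genome build GRCh38 are named in the submitters' processing notes, without their roles. The counting tool, the strand setting and the annotation release are not given in the sources used here. Reads of overlapping, antisense or near-identical genes could therefore have been split between them in ways that cannot be checked.

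The deposited table held 58395 genes by Ensembl identifier. Per the file headers, the authors gave 1 FPKM value (fragments per kilobase of gene, relative to all mapped fragments) per gene and library. FPKM is scaled within each library and corrects for gene length, but no scaling between libraries is recorded. The same deposited table held the authors' own comparison of both groups: a mean normalized count, a log2 fold change with its standard error, a test score and p-values, per the file headers. No tool for that comparison is given in the sources used here. Values from it are named as such wherever they are printed. Chromosomes and strands came from GENCODE release 29 on GRCh38, which held 58275 of the identifiers, with the same gene start for 49009 of them.

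The FPKM values summed to between 229485 and 268612 per library. Whole reads could not be recovered from them, so no count test was run. In genes detected in a single library, the deposited mean normalized counts fell on whole multiples of a step for each library (100% of values within 0.01). Those steps gave relative size factors of 1.00, 0.995 and 0.927 for sgControl replicates 1 to 3 and 0.997, 1.08 and 1.09 for sgPLOD2. The largest was 1.18 times the smallest, and such factors depend on the composition of a library as well as on its number of reads. Absolute depth per library is unknown, and no counting interval is given. An FPKM of exactly 0 could be a failed estimate, so such genes are described as listed at 0.

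FPKM values as deposited were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). The 10469 genes with a mean of at least 1 FPKM over all 6 libraries were tested, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are sgPLOD2 minus sgControl on this log2 scale, which understates changes of weakly expressed genes. The targeted gene was also compared with an exact permutation test in scipy 1.17.1. Of 35 gene lists, the 31 with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01, adjusted over those lists. The lists were drawn up from textbook knowledge, without PLOD2. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera also takes its degrees of freedom from the few libraries, so a list can lose its call whatever its correlation. Camera compares a list with the other genes, whereas fry tests it against no change, so their p-values answer different questions. The design, the lists, the rule for named genes and all alternatives except 2 were fixed before the data were examined.

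The genes named were PLOD2, the 12 largest fold changes in each direction among called, non-overlapping genes with a proper symbol, and the 5 largest FPKM differences in each direction. For each list described in detail, its 4 members with the smallest adjusted p and its best known markers were added. Lists described in detail were the 8 that camera called and 7 on collagen, matrix, epithelium, kidney and HIF targets. Some genes that this rule picked are not reported here. Any other gene was named after its values had been seen.

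The limma steps were tested on simulated data for this comparison, with 67, 67 and 66 genes changed by 0.5, 1 and 2 on the log2 scale among 10469. They recovered 29.9% of genes changed by 0.5, 92.5% of those changed by 1 and 100% of those changed by 2, and 6.3% of calls were false. Far fewer genes changed there than were called in the data, so these shares need not hold for the real calls. Camera called the planted list and 0 of 19 others. The simulated noise was independent between genes, so this could not show false list calls that come from correlated genes.

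The alternatives were pseudocounts of 0.1 and 0.5, no filter, a minimum of 5 FPKM, rescaling to the same total per library (TPM), TPM without mitochondrial and ribosomal protein genes, median-of-ratios scaling and quantile normalization. Variance models without the trend or with robust estimation, the replicate number as a block, a fold threshold and leaving out each library in turn were also run. Removal of a smooth trend of fold change on GC content and transcript length (mgcv 1.9.3) and removal of each chromosome's median fold change were chosen after seeing the data. GC content and length were known for 99.9% of tested genes. Chromosome medians were compared with 10000 shuffles of gene positions (numpy 2.4.6), and figures were drawn with matplotlib 3.10.9.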

Results

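The series asked how the loss of PLOD2 alters the transcriptome of 786-O cells, a human line from a clear cell renal carcinoma that lacks functional VHL and is known to make HIF-2α but no HIF-1α protein. Its title places the work in the search for treatments that make sarcomatoid renal carcinoma cells differentiate. PLOD2 encodes lysyl hydroxylase 2, which hydroxylates collagen lysines before cross-linking. RNA was sequenced from 3 libraries of cells carrying a control guide (sgControl) and 3 of cells in which PLOD2 had been targeted with CRISPR/Cas9 (sgPLOD2). Between 9874 and 10649 genes reached 1 FPKM per library. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Besides PLOD2, the groups differed in HIF1A and along chromosomes or parts of them, as described below, so they may hold different cell populations. The design does not separate such a difference from an effect of PLOD2 loss, also for the level of PLOD2 mRNA itself.

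PLOD2 mRNA fell in sgPLOD2. PLOD2 (ENSG00000152952; GRCh38, chromosome 3, 146069440 to 146163653, minus strand, protein-coding) averaged 24.7 ± 2.80 FPKM (SD, n = 3) in sgControl and 7.57 ± 2.21 FPKM (SD, n = 3) in sgPLOD2. Single libraries gave 26.8, 25.7 and 21.5 FPKM in sgControl and 5.98, 10.1 and 6.64 FPKM in sgPLOD2, so 30.7% of the control level remained. The log2 fold change on log2(FPKM + 1) was -1.61 ± 0.18 (SE), with a limma adjusted p of 0.000509. The 2-sided exact permutation test gave p = 0.1, the smallest it can give with 3 libraries against 3.

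The difference between both groups was broad and included genes close to absent on either side. Among the largest rises were the amino acid transporter SLC38A5, the surface glycoprotein podoplanin (PDPN), the proteoglycan serglycin (SRGN), the hypoxia-inducible factor subunit HIF1A, the secreted matrix protein CTHRC1 and the fatty acid desaturase SCD. Among the largest falls were the chemerin gene RARRES2, the interferon-stimulated genes IFI27, BST2, IFI6 and ISG15, the chemokine gene CCL20 and the DNA repair gene MGMT. In all, 3084 of 10469 genes rose and 2456 fell at an adjusted p under 0.05, of which 527 and 409 changed by at least 1 on the log2 scale. That made 55.7% of calls higher, against 66.8% under TPM, 63.9% under TPM without mitochondrial and ribosomal protein genes, 49.9% under both median-of-ratios scaling and quantile normalization, and 45.2% at a minimum of 5 FPKM. The median fold change of all tested genes was 0.06 as deposited and 0.20 under TPM. Correlations of log2 values across genes, which are not independent replicates, were 0.971 to 0.987 within groups and 0.898 to 0.927 between them.

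SLC38A5 went from 0.0523 ± 0.0333 to 47.3 ± 3.58 FPKM (SD, n = 3 each; log2 fold change 5.52, adjusted p = 6.29e-07). HIF1A (chromosome 14, 61695513 to 61748259) went from 0.420 ± 0.115 to 37.7 ± 1.84 FPKM, with a log2 fold change of 4.77 and an adjusted p of 9.93e-07. PDPN was listed at 0 in every sgControl library and had 51.1, 50.9 and 22.0 FPKM in sgPLOD2. CTHRC1 rose from 3.60 ± 0.34 to 95.3 ± 10.3 FPKM and SCD from 3.45 ± 0.41 to 72.0 ± 3.32 FPKM. SRGN, the basement membrane gene NID2, CHRDL1, CRISPLD2 and SCARA3 rose by 4.98, 3.66, 3.54, 3.5 and 3.14 on the log2 scale. The cancer-testis genes SPANXA2 and SPANXA1 also rose (5.37 and 5.31), but they are near-identical copies whose reads may have been shared. RARRES2 fell from 176 ± 15.1 to 2.57 ± 0.56 FPKM (log2 fold change -5.64, adjusted p = 9.93e-07). MGMT fell from 11.4 ± 0.92 to 0.0247 ± 0.0106 FPKM and CCL20 from 15.1 ± 0.77 to 0.349 ± 0.042 FPKM. SCARF2, the sulfotransferase gene GAL3ST1, the thymidine phosphorylase gene TYMP, LAYN and the pseudogene CLEC4O fell, with log2 fold changes of -4.01, -3.94, -3.65, -3.63 and -3.59.

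In absolute FPKM, the largest gains were in the tubulin gene TUBB (778 to 1081), the chaperone gene HSP90AB1 (747 to 1028), the ribosomal protein gene RPS4X (205 to 491), the moesin gene MSN (134 to 368) and EEF1A1 (618 to 897). TUBB and HSP90AB1 lie on chromosome 6, and with chromosome medians removed their log2 fold changes went from 0.48 to 0.19 (adjusted p = 0.123) and from 0.46 to 0.17 (adjusted p = 0.117). EEF1A1 had an adjusted p of 0.0472, and leaving out sgControl replicate 2 or 3, or any sgPLOD2 library, gave 0.0811 to 0.126. It was not called either with chromosome medians removed (0.273), with the GC and length trend removed (0.178), with no filter (0.129) or with median-of-ratios scaling (0.0733). The largest losses were in the mitochondrial genes MT-CO2, MT-CO1, MT-CO3 and MT-ND2 and in the small heat shock gene HSPB1 (1380 to 729). With the GC and length trend removed, HSPB1 went from a log2 fold change of -0.90 to -0.34 (adjusted p = 0.0961).

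**Figure D1:**
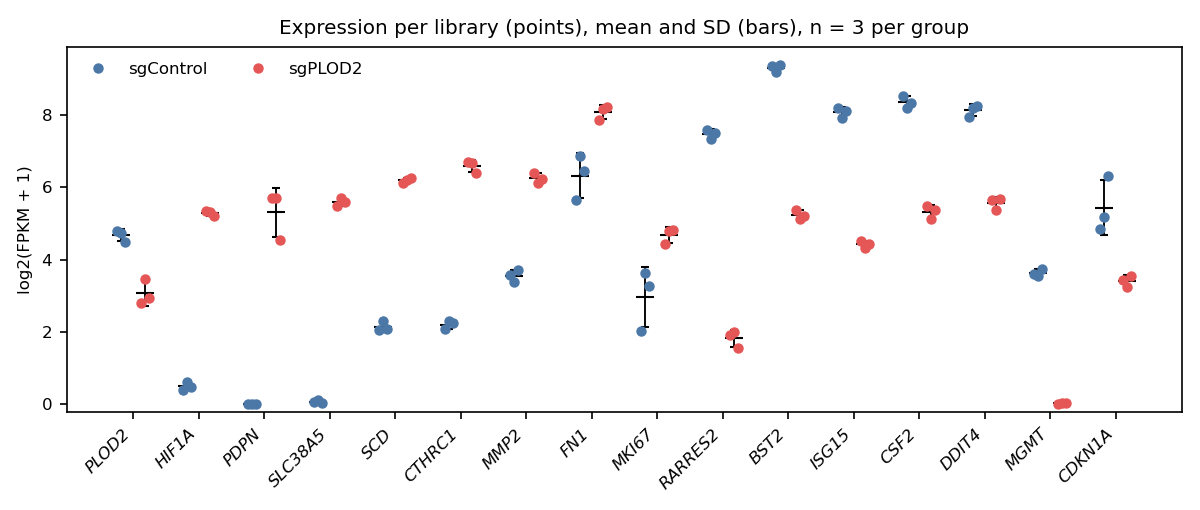
Expression of 16 genes in each library as log2(FPKM + 1). Points are single libraries, and bars give the mean and SD of 3 libraries per group. HIF1A, PDPN and SLC38A5 were near 0 in all sgControl libraries, while MGMT was near 0 in all sgPLOD2 libraries.

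Most tested interferon-stimulated genes and inflammatory mediators fell. Of 41 tested interferon-stimulated genes, which are induced by interferon signalling, 33 fell and 1, HERC5, rose, and the same numbers passed when adjusted over the list alone. BST2, which tethers budding virus, fell from 627 ± 44.3 to 36.6 ± 3.33 FPKM, IFI6 from 315 ± 7.59 to 22.0 ± 2.37 FPKM and the ubiquitin-like modifier ISG15 from 267 ± 25.1 to 20.4 ± 1.35 FPKM (SD, n = 3 each). The antiviral genes OAS2 and MX1 fell, with log2 fold changes of -3.14 and -2.91. The list median was -1.32 and camera gave an adjusted p of 7.81e-15 (adjusted p = 0.0856 with an estimated correlation). Of 31 NF-kB targets and inflammatory mediators, 22 fell and 3 rose, also when adjusted over the list alone. The cytokine gene CSF2 fell from 323 ± 38.2 to 39.2 ± 4.93 FPKM, CXCL2 from 28.8 ± 2.30 to 4.04 ± 0.10 FPKM, CXCL1 from 335 ± 41.2 to 147 ± 9.24 FPKM and TNFAIP6 from 9.87 ± 1.55 to 0.104 ± 0.065 FPKM. Camera gave an adjusted p of 2.22e-06 for this list, with a median of -0.86 (adjusted p = 0.0856 with an estimated correlation). IL11, VCAM1 and CCL2 rose. Of 20 class I antigen presentation genes, 2 rose and 9 fell, over all genes as adjusted over the list alone, and camera did not call the list (adjusted p = 0.245). Fry gave that list an adjusted p of 0.0290 on the lower side.

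More cell cycle genes rose than fell, while more p53 targets and ATF4 targets fell than rose. Of 44 G2/M genes, 25 rose and 3 fell (UBE2C, MYBL2 and PLK1), also when adjusted over the list alone. The mitotic kinesin gene KIF4A rose from 17.4 ± 2.28 to 59.2 ± 2.27 FPKM, the cyclin gene CCNA2 from 25 ± 1.99 to 56.2 ± 4.22 FPKM and the topoisomerase gene TOP2A from 17.1 ± 3.78 to 43.3 ± 5.05 FPKM (SD, n = 3 each). DLGAP5, KIF23 and the proliferation marker MKI67 rose by 1.36, 1.13 and 1.71 on the log2 scale. The list median was 0.57 and the camera adjusted p 0.00460 (adjusted p = 0.612 with an estimated correlation). Of 43 S phase and replication genes, 22 rose and 2 fell, also when adjusted over the list alone. MCM10, GINS3, MCM3 and MCM6, which act at replication origins, rose by 1.21, 1.00, 0.91 and 0.78, whereas E2F1 and CDT1 fell. MCM2 had 34.0 ± 7.27 and 42.2 ± 2.34 FPKM and was not called, except with quantile normalization (adjusted p = 0.0496) and with the GC and length trend removed (0.0421). The camera adjusted p was 0.0259 (adjusted p = 0.506 with an estimated correlation).

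Of 26 p53 targets, 13 fell and 2 rose, or 15 and 2 when adjusted over the list alone. The stress cytokine gene GDF15 fell from 11.4 ± 2.07 to 0.23 ± 0.04 FPKM, the proapoptotic gene BAX from 52.9 ± 3.29 to 21.1 ± 0.83 FPKM and the cell cycle inhibitor gene CDKN1A from 46.7 ± 26.8 to 9.62 ± 1.15 FPKM (SD, n = 3 each). PHLDA3 and BBC3 fell, with log2 fold changes of -2.03 and -2.08, and MDM2 was not called (adjusted p = 0.320, or 0.0138 with the GC and length trend removed). Camera gave an adjusted p of 0.000717 (adjusted p = 0.204 with an estimated correlation). Of 32 ATF4 targets of the integrated stress response, 15 fell and 4 rose, or 16 and 4 when adjusted over the list alone. ATF4 itself fell from 219 ± 13 to 101 ± 7.74 FPKM, and the amino acid transporter subunits SLC7A5 and SLC3A2 and the mTORC1 inhibitor gene DDIT4 fell, with log2 fold changes of -2.09, -1.38 and -2.57. ATF3, at 2.94 ± 2.05 and 1.77 ± 0.26 FPKM, was not called. Camera gave an adjusted p of 0.000717 (adjusted p = 0.329 with an estimated correlation). GDF15 belonged to both lists.

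Mesenchymal markers rose on balance, while collagen genes and their modifying enzymes moved both ways. Of 20 mesenchymal markers, 13 rose and 2 fell, or 14 and 2 when adjusted over the list alone. The gelatinase gene MMP2 rose from 10.7 ± 1.37 to 75.2 ± 7.12 FPKM, the cadherin gene CDH11 from 0.165 ± 0.045 to 4.86 ± 0.41 FPKM and WNT5A from 2.03 ± 0.13 to 14.6 ± 1.56 FPKM (SD, n = 3 each). WNT5B rose by 1.69 on the log2 scale. CDH2 had 54.9 ± 10.7 and 81.1 ± 6.13 FPKM (adjusted p = 0.0159, or 0.0590 without sgPLOD2 replicate 2, 0.0902 with the GC and length trend removed and 0.0534 with chromosome medians removed). The vimentin gene VIM had 1120 ± 186 and 867 ± 20.3 FPKM, with an adjusted p of 0.0474 that was 0.0689 without sgControl replicate 3 and 0.0912 to 0.127 without any 1 of the sgPLOD2 libraries. VIM was not called either with no filter (0.126), under TPM (0.0816) or under TPM without mitochondrial and ribosomal protein genes (0.0745). TAGLN fell by 1.55. The camera adjusted p of the list was 0.00320, with a median of 0.58 (adjusted p = 0.201 with an estimated correlation).

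Of 27 matrix glycoproteins and integrins, 15 rose and 5 fell, also when adjusted over the list alone, and camera did not call the list (adjusted p = 0.110), though it did with no filter (0.0145), at a minimum of 5 FPKM (0.0468) and with quantile normalization (0.0203). The nidogen genes went apart, NID2 up from 1.03 ± 0.24 to 24.6 ± 1.92 FPKM and NID1 down from 6.44 ± 1.69 to 0.515 ± 0.057 FPKM (SD, n = 3 each). Fibronectin (FN1) rose from 83.4 ± 33.2 to 270 ± 33.7 FPKM and SPARC by 0.80 on the log2 scale, whereas AGRN fell by 0.97. Of 12 collagen chain genes, 6 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.681). With fry, collagen chains and the matrix list each had an adjusted p of 0.0381 on the higher side. COL6A1 rose from 35.8 ± 1.93 to 82.2 ± 5.55 FPKM, COL1A1 from 0.489 ± 0.069 to 2.94 ± 0.21 FPKM and COL12A1 by 1.59 on the log2 scale, whereas COL5A2 fell from 4.72 ± 1.42 to 0.129 ± 0.015 FPKM. Of 23 collagen-modifying and cross-linking enzymes, 7 rose and 10 fell, or 8 and 10 when adjusted over the list alone (camera adjusted p = 0.336). The cross-linking oxidase LOXL1 rose from 8.43 ± 0.45 to 33.7 ± 2.84 FPKM. Both other lysyl hydroxylase genes fell, PLOD1 from 92.5 ± 1.96 to 60.5 ± 2.91 FPKM and PLOD3 from 74.6 ± 2.73 to 35.9 ± 1.66 FPKM. The prolyl hydroxylase subunit gene P4HB and P3H3, of a separate prolyl hydroxylase family, fell as well, with log2 fold changes of -0.85 and -0.75.

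Camera did not call markers of epithelial and renal identity in the planned fit. Of 37 epithelial markers only 13 were tested, so most members do not enter this result. Of these 13, 4 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.807). The tricellular junction gene LSR rose from 1.91 ± 0.37 to 11.5 ± 1.99 FPKM and CLDN1 by 0.80 on the log2 scale, whereas PKP3 and ELF3 fell (-1.04 and -0.76). Of 12 proximal tubule genes, 4 rose and 5 fell, or 5 and 5 when adjusted over the list alone (camera adjusted p = 0.582; fry, on the lower side, 0.000562). The gamma-glutamyltransferase gene GGT1 fell from 51.8 ± 5.75 to 7.30 ± 0.13 FPKM and PDZK1IP1 from 66.9 ± 5.47 to 22.0 ± 1.80 FPKM (SD, n = 3 each). ENPEP fell by 1.46 on the log2 scale, and the transporter gene SLC16A9 rose from 0.0291 ± 0.0194 to 2.81 ± 0.53 FPKM. Of 18 renal progenitor and developmental genes, 10 rose and 2 fell, or 11 and 2 when adjusted over the list alone, with a camera adjusted p of 0.0765 (0.0466 without sgPLOD2 replicate 1 and 0.00301 with no filter on low values). Against no change, fry gave this list an adjusted p of 0.000941 on the higher side. The homeobox genes LHX1 and HOXC10 rose by 1.51 and 0.73 and the zinc finger gene SALL1 by 0.92 on the log2 scale. PAX8, a lineage factor of renal carcinoma, had 28.0 ± 7.27 and 24 ± 2.35 FPKM and was not called. PAX2 had 1.88 ± 0.19 and 1.28 ± 0.13 FPKM, with an adjusted p of 0.0191 that was 0.0533 to 0.0670 without sgControl replicate 3, sgPLOD2 replicate 1 or sgPLOD2 replicate 2. Under TPM it was 0.0538, and with the GC and length trend removed the log2 fold change of PAX2 went from -0.33 to -0.07 (adjusted p = 0.579).

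**Figure D2:**
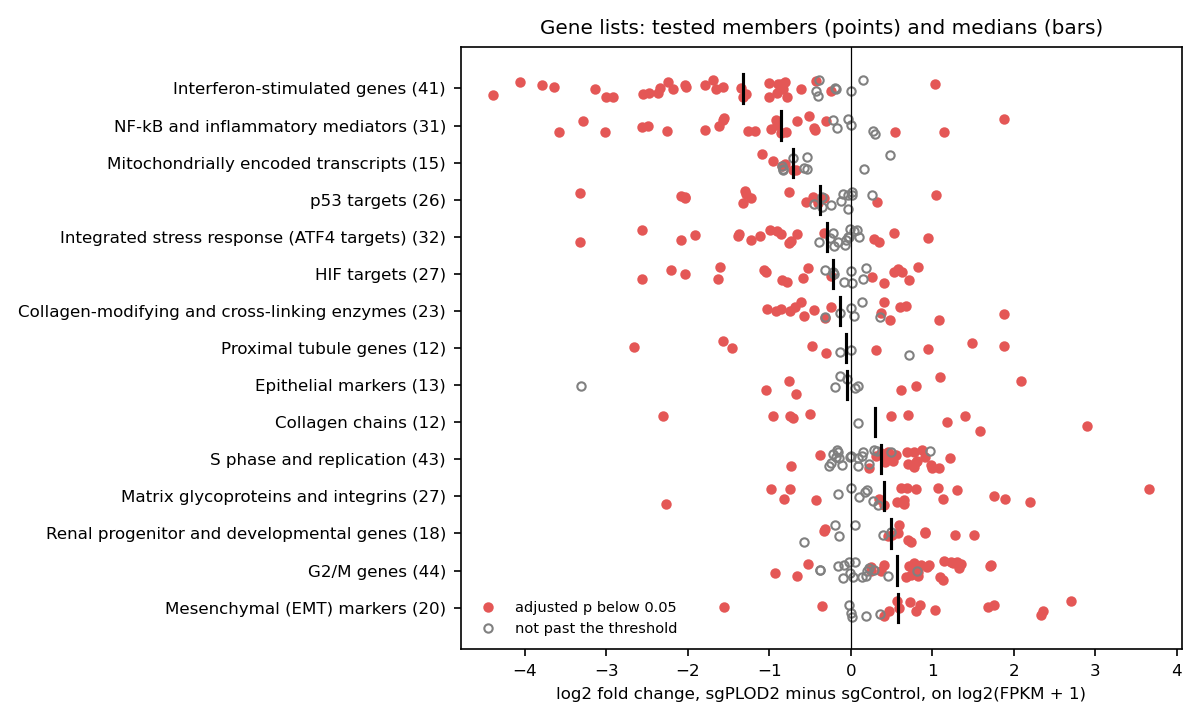
Log2 fold change, sgPLOD2 minus sgControl on log2(FPKM + 1), of the tested members of 15 gene lists, with the number tested in brackets. Filled points passed an adjusted p of 0.05, open points did not, and black bars mark list medians, from -1.32 for interferon-stimulated genes to 0.58 for mesenchymal markers.

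HIF targets moved both ways, with more falls than rises, and 6 of 15 mitochondrially encoded transcripts were called lower. Of 27 HIF targets, 12 fell and 7 rose, also when adjusted over the list alone. The carbonic anhydrase gene CA12 fell from 31.9 ± 2.54 to 9.65 ± 1.17 FPKM, the lipid droplet gene HILPDA from 31.9 ± 7.19 to 6.87 ± 0.31 FPKM and the oxygen sensor gene EGLN3 from 6.88 ± 2.13 to 0.674 ± 0.067 FPKM (SD, n = 3 each). The camera adjusted p was 0.0769, and it passed the threshold without sgControl replicate 1 (0.0496), with the GC and length trend removed (0.00303) and with chromosome medians removed (0.0183). Fry, against no change, gave an adjusted p of 0.000918 on the lower side. Of 15 mitochondrially encoded transcripts, 6 fell and 0 rose, or 3 and 0 when adjusted over the list alone, with a median of -0.71 and a camera adjusted p of 0.0326 (adjusted p = 0.716 with an estimated correlation). MT-CO1 had 2604 ± 1059 and 1283 ± 66.9 FPKM, MT-CO3 2754 ± 944 and 1515 ± 63.8 FPKM, and MT-ND3 976 ± 191 and 608 ± 40.1 FPKM. Mitochondrial genes made up 12.9% of FPKM in sgControl replicate 1 and 6.01% to 7.5% in the other libraries. MT-CO2 and MT-ND2 were not called without any 1 of the sgPLOD2 libraries, where adjusted p was 0.0858 to 0.105 and 0.0839 to 0.0958, with log2 fold changes close to the planned -0.70 and -1.09. Without sgControl replicate 1, MT-CO2 and MT-ND2 were called with smaller changes (-0.41 and -0.62), as were MT-CO1 (-0.64) and MT-CO3 (-0.54). MT-CO1 (0.0502 without sgPLOD2 replicate 2), MT-CO3 (0.0631 without sgPLOD2 replicate 3) and the list (0.0519 without sgPLOD2 replicate 3, 0.0504 with median-of-ratios scaling, 0.103 with quantile normalization, 0.105 at a minimum of 5 FPKM and 0.192 with fry) also lost their calls. With no filter on low values MT-CO1 (0.0614), MT-CO2 (0.123), MT-CO3 (0.0644) and MT-ND2 (0.110) were not called, nor was MT-CO2 with quantile normalization (0.385) or MT-ND2 with robust estimation (0.0505).

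The remaining lists were not called by camera in the planned fit, though some passed under alternatives. Among metabolic lists, 4 glycolysis genes rose and 7 fell of 22 (adjusted p = 0.582), 5 fatty acid oxidation genes rose and 10 fell of 23 (adjusted p = 0.157), 8 lipid droplet and lipogenesis genes rose and 7 fell of 22 (adjusted p = 0.848), and 5 cholesterol synthesis genes rose and 7 fell of 23 (adjusted p = 0.295). Of 50 nuclear-encoded oxidative phosphorylation genes, 7 rose and 10 fell (adjusted p = 0.336). When adjusted over the list alone these numbers were the same, except for lipid droplet genes (8 and 8) and oxidative phosphorylation (6 and 9). Among signalling lists, 16 TGF-beta targets rose and 7 fell of 30 (adjusted p = 0.173), 15 YAP/TAZ targets rose and 4 fell of 24 (adjusted p = 0.0765), 6 MAPK/ERK output genes rose and 3 fell of 21 (adjusted p = 0.568), 3 Wnt targets rose and 2 fell of 8 (adjusted p = 0.518), and 1 Notch gene rose and 3 fell of 7 (adjusted p = 0.0835). When adjusted over the list alone, 15 and 5 YAP/TAZ targets and 5 and 3 MAPK/ERK genes passed, with the other counts the same. YAP/TAZ targets passed the camera threshold without sgControl replicate 2 (0.0392), without sgPLOD2 replicate 1 (0.0464), with no filter (0.0184), at a minimum of 5 FPKM (0.0468) and with quantile normalization (0.0193). TGF-beta targets passed with no filter (0.0321) and with quantile normalization (0.0314), and fatty acid oxidation genes, on the lower side, with the GC and length trend removed (0.0319) and with chromosome medians removed (0.0327). Fry tests against no change and called 22 of the 31 lists, so passing it says little about any 1 list. By fry, Wnt targets (0.000562), TGF-beta targets (0.00131), lipid droplet genes (0.0127), MAPK/ERK genes (0.0127) and YAP/TAZ targets (0.0437) passed on the higher side. Notch (0.000221), fatty acid oxidation (0.00383) and cholesterol synthesis genes (0.0389) passed by fry on the lower side.

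Among stress and growth lists, 6 unfolded protein response genes rose and 6 fell of 24 (adjusted p = 0.848), 5 NRF2 targets rose and 5 fell of 20 (adjusted p = 0.681), 17 ribosome biogenesis genes rose and 5 fell of 38 (adjusted p = 0.189), 14 ribosomal protein genes rose and 7 fell of 65 (adjusted p = 0.848), and 4 stem-cell-associated genes rose and 2 fell of 10 (adjusted p = 0.564). When adjusted over the list alone, 10 and 6 ribosomal protein genes and 5 and 2 stem-cell-associated genes passed, with the other counts the same. Medians and means differed in sign for glycolysis (0.04 and -0.03), lipid droplet genes (-0.07 and 0.18), NRF2 targets (-0.07 and 0.04) and ribosomal proteins (-0.08 and 0.05), and camera placed all of these on the lower side. With quantile normalization, ribosome biogenesis genes (0.0124) and ribosomal protein genes (0.00276) passed on the higher side. Ribosome biogenesis genes also passed by fry on that side (0.00131). Too few members of 4 lists were expressed for a set test. Of 3 replication-dependent histones, H2AC17 rose, and 1 and 1 passed when adjusted over the list alone. Of the markers of other cell types, CSF1R rose and CD68 fell among 2 haematopoietic genes tested, EGFL7 fell as the 1 endothelial gene tested, and COL1A1 rose as the 1 fibroblast gene tested, each also when adjusted over the list alone.

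Fold changes also differed by chromosome, which was examined after the calls had been seen. On chromosome 14, 234 of 344 tested genes rose and 23 fell, with a median log2 fold change of 0.54, and NID2 and DLGAP5 lie there, as does IFI27, which fell. Medians were 0.35 on chromosome 6, 0.33 on chromosome 3, -0.25 on chromosome 16 and -0.21 on chromosome 22. For each of these 5 chromosomes, 10000 shuffles of gene positions gave the smallest p they can give (0.0001, adjusted p = 0.0003 over 23 chromosomes). The shuffles treat neighbouring genes as independent and leave out the spread between libraries, so these p-values may be too small. With the trend on GC content and length removed, the medians were 0.49, 0.30, 0.25, -0.15 and -0.13. The lowest was then chromosome 13 (-0.12 before, -0.30 after), and chromosome 19 went from -0.18 (adjusted p = 0.0003) to 0.08 (adjusted p = 0.330). HIF1A's neighbours were low in sgControl as well. SNAPC1, a subunit of the snRNA-activating complex, had 0.979 ± 0.283 and 7.62 ± 0.53 FPKM, the noncoding AL355916.1 had 0.659 ± 0.187 and 3.90 ± 0.45 FPKM (SD, n = 3 each), and AL355916.3, which overlaps it, was listed at 0 in every sgControl library. Further upstream, SLC38A6 had 0.997 ± 0.083 and 0.978 ± 0.060 FPKM, while TRMT5 (1.02 and 2.78 FPKM) and MNAT1 (2.48 and 4.45 FPKM) were higher in sgPLOD2.

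**Figure D3:**
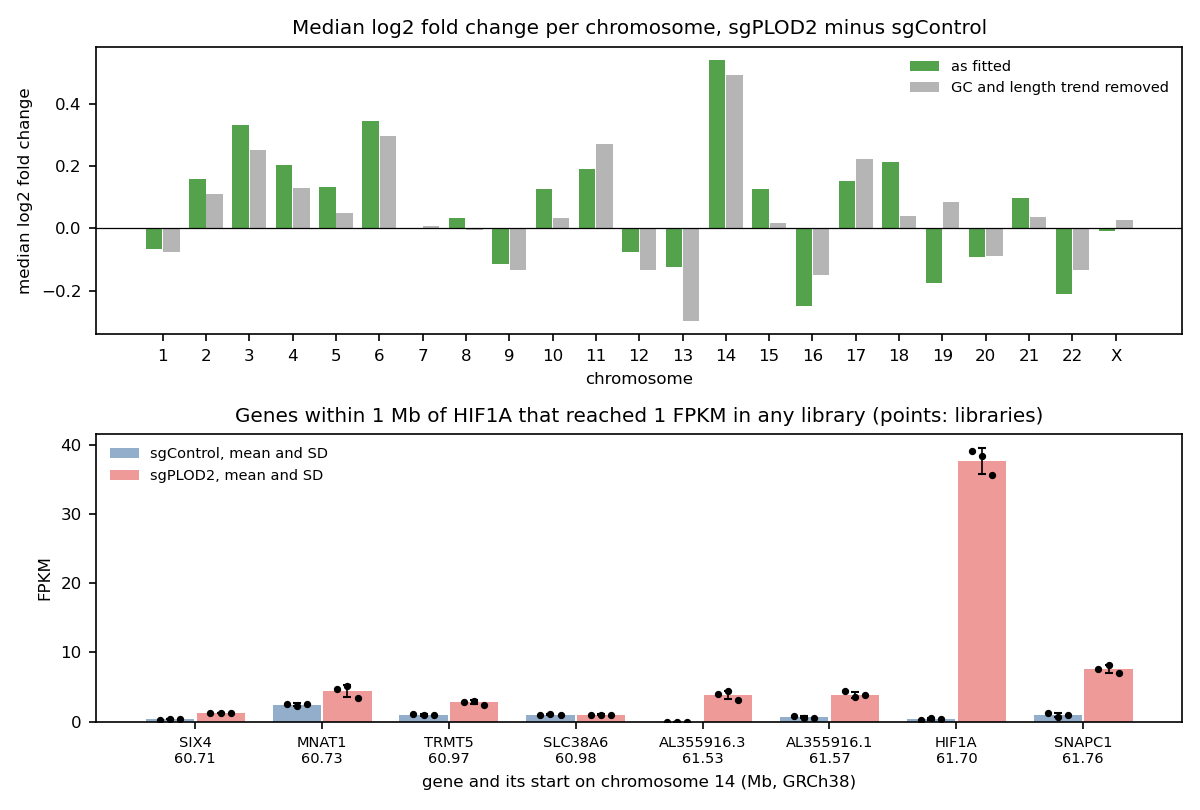
Top, median log2 fold change of tested genes on each chromosome, as fitted and with the trend on GC content and length removed; the highest is chromosome 14 at 0.54. Bottom, FPKM of genes within 1 Mb of HIF1A in both groups, with bars for the mean, error bars for the SD and points for the 3 libraries of each group.

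The authors' deposited table gave an adjusted p for 22870 genes and called 8124 at 0.05, 4240 higher and 3884 lower. In the authors' deposited table, 2261 of the higher and 1715 of the lower genes changed by at least 1 on the log2 scale. Of the genes tested here, 4932 were called both here and in the authors' deposited table, all with the same sign, while 608 were called only here and 376 only there.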

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

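The count of other splits, the removal of chromosome medians and the look at the HIF1A block were chosen after the results were seen. No prediction was written beforehand for the genes under the filter. The other tests in this part were written before the results they measure, but for patterns already seen in the planned fit. The bound for interferon-stimulated genes was set from their list median in that fit. Genes under the filter of 1 FPKM were not tested in the planned fit, and some of them had signal on 1 side alone. Among them, 11 genes were listed at 0 in every sgControl library and had at least 0.5 FPKM in every sgPLOD2 library, among them PRKCZ and SCD5, and 8 showed the opposite, among them XAF1. The highest count in the other 9 splits of the libraries was 1. Those splits mix both groups on each side, where a gene that differs by group cannot meet the rule, so that count decides nothing. The HIF target CA9 was listed at 0 in all sgControl libraries and averaged 0.324 FPKM in sgPLOD2.

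The difference between both groups was broad, and unrelated genes moved in part with their position. With chromosome medians removed, 5015 genes were still called, 4279 of them among the 5540 of the planned fit. That removal leaves shifts of regions within a chromosome, so the share of the breadth that goes with position was not measured. Cells of another line, or a diverged clone, behind 1 group would shift unrelated genes together along chromosomes. The SD of the chromosome medians was 0.195, against at most 0.0682 in 10000 shuffles, as this explanation requires. The shuffles treat neighbouring genes as independent, so the SD alone does not single out this explanation. A bias by GC content or gene length as the whole cause of the differences between chromosomes was argued against. With that trend removed the SD was still 0.178, above the highest of its shuffles (0.0637). The SD measures position, not the number of calls. With the GC and length trend removed, 4662 genes were called, 3731 of them among the 5540 of the planned fit. Log2 fold changes correlated with GC content across genes (-0.3). A part of the breadth could therefore go with GC content or length, and its share was not measured. Of the 10 splits of the 6 libraries, 1 gave as many calls, the real one with 5540, and the highest of the others gave 1. The others mix both groups on each side, so the group difference adds to their spread and keeps their calls low in advance. With 10 splits too few for a share under 0.05 as well, this decides nothing. The low HIF1A block in sgControl fits the known lack of HIF-1α in 786-O cells, so a candidate explanation is that the sgPLOD2 libraries come from cells of another origin or a distant clone; an effect of PLOD2 loss stays open and was not separated from it.

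The fall of interferon-stimulated genes could reflect the loss of PLOD2 or a difference between the cell populations, which the design does not separate. A bias by GC content or length was argued against by the list median, -1.22 with the trend removed and -1.32 before. RNA of blood cells in the sgControl libraries was argued against by 6 blood markers, PTPRC, CD3E, CD14, LYZ, LAPTM5 and CD52, whose median in sgControl was 0.0082 FPKM.

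The lower mitochondrial transcripts rest partly on sgControl replicate 1. Without that library the list median was -0.40, between the bounds set for an effect of that library alone and for none. Under the other scalings the value nearest to 0 was -0.47, with quantile normalization, and the farthest was -0.78, so a part due to scaling and a part due to that library cannot be told apart from a difference between groups. PLOD2 loss as a biological explanation was not tested.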

How the results depend on the processing

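Removal of the GC and length trend and of chromosome medians was chosen after seeing the data. PLOD2 stayed lower and past the threshold under all 19 alternatives, with log2 fold changes from -1.88 to -1.47. Leaving out 1 library gave 2307 to 3228 higher and 1920 to 2572 lower genes. A minimum of 5 FPKM, with fewer genes tested, gave 1361 higher and 1649 lower genes, the reverse of the planned balance, and a fold threshold of 1 left 527 higher and 409 lower. The replicate numbers did not pair the libraries (correlations of same-numbered deviations 0.014, 0.135 and -0.049, and sgControl replicates 1 and 3 correlated best with another number); with the replicate number as a block, 2984 genes were higher and 2335 lower, 5319 in all, and camera called YAP/TAZ targets (0.0377). Camera called 8 lists, 14 with no filter, 7 to 10 with 1 library left out and 0 with an estimated correlation, where 4 passed an unadjusted p of 0.05. For NF-kB and inflammatory mediators and for mesenchymal markers the estimates (0.00717 and 0.000226) were below the preset 0.01. A higher correlation was therefore not why these lists lost their calls. The other called lists had estimates above the preset, up to 0.955 for mitochondrial transcripts. Fry called 22 lists directionally and 30 for change in either direction. Apart from mitochondrial transcripts, each called list was called in all 19 other camera fits at the preset correlation. The cause of the following reversals was not tested. The log2 fold changes of uncalled ATF3 and PAX8 turned above 0 without sgControl replicate 3 and 1, ranging with 1 library left out from -0.697 to 0.00737 and from -0.309 to 0.00770. Lists that camera did not call turned direction, with these adjusted p: with quantile normalization, epithelial markers (0.835), glycolysis (0.538), lipid droplet genes (0.816), NRF2 targets (0.818), oxidative phosphorylation (0.816) and ribosomal proteins (0.00276, past the threshold); at a minimum of 5 FPKM, epithelial markers (0.670), NRF2 targets (0.876) and ribosomal proteins (0.605); with TPM, ribosomal proteins (0.756); with the GC and length trend removed, lipid droplet genes (0.783), NRF2 targets (0.821), ribosomal proteins (0.428) and the unfolded protein response (0.789); with chromosome medians removed, ribosomal proteins (0.865); with no filter, the unfolded protein response (0.962); with fry, lipid droplet genes (0.0127), NRF2 targets (0.313), ribosomal proteins (0.599) and stem-cell-associated genes (0.101). Leaving out 1 library turned epithelial markers (0.533 to 0.995 over the 6 fits), ribosomal proteins (0.333 to 0.959) and the unfolded protein response (0.652 to 0.983) in some fits. Of 101 named genes, 16 changed side or direction under any alternative. Absolute depth per library is unknown, and among simulated changes of 0.5 on the log2 scale 29.9% were recovered.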

Other observations

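The test of HIF targets, its gene sets and the choice of genes in this part came after the results were seen. Some genes were close to absent in 1 group only. Below 0.1 FPKM in all sgControl libraries and at least 1 FPKM in all sgPLOD2 libraries were 41 genes, 37 of them protein-coding. They included the transcription factor genes GATA3 (1.31 to 1.71 FPKM in sgPLOD2), TFAP2C (3.13 to 3.51), POU3F3 (2.82 to 3.26) and NR0B1 (2.64 to 2.81), and the cancer-testis genes XAGE1A, XAGE1B and GAGE2A, whose near-identical copies may share reads (XAGE1A 2.66 to 3.57). The opposite held for 32 genes, 29 of them protein-coding, including the kinase gene SYK (1.82 to 2.59 FPKM in sgControl), the potassium channel gene KCNH2 (3.45 to 3.95), UPK1B (7.03 to 10.1) and PODXL2 (5.59 to 7.57). The epithelial marker DSP, which was under the filter, was also among them (1.02 to 1.64 FPKM in sgControl).

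The windows of 50 consecutive tested genes with the highest medians lay on chromosome 14, led by the one from 60.1 to 73.0 Mb with a median of 0.79 and 47 of 50 genes above 0. With the GC and length trend removed its median was 0.62, and the one from 73.0 to 88.9 Mb led with 0.67. On chromosome 3, the window from 15.2 to 39.2 Mb had a median of 0.61, and 1 on chromosome 6 from 98.9 to 122.5 Mb had all 50 genes above 0. Chromosome 3 also carries PLOD2, but the windows that hold it had lower medians, 0.19 from 136.1 to 155.9 Mb and 0.08 from 144.0 to 169.8 Mb. The lowest lay on chromosome 9 from 133.5 to 137.2 Mb (-0.69, or -0.40 with the GC and length trend removed, when 1 on chromosome X from 136.7 to 154.4 Mb was lowest at -0.45). Parts of 1 chromosome could go opposite ways. The first window of chromosome 9, up to 33.3 Mb, had a median of 0.54, or 0.37 with the trend removed.

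HIF targets were also sorted by the factor they are known to prefer. Of 15 targets known mainly from HIF-1, 7 rose and 3 fell, with a median of 0.26, among them BNIP3 (0.63), HK2 (0.82) and LDHA (0.46). Of 12 known mainly from HIF-2 in renal carcinoma, 0 rose and 8 fell, with a median of -0.81, among them EGLN3 (-2.20), NDRG1 (-1.61) and TGFA (-1.04). The medians differed by 1.07 (2-sided permutation test, p = 0.00268, genes not being independent replicates). This decides nothing, since both sets were drawn up after the values were seen and left out HIF targets that fell, such as DDIT4 (-2.57) and HILPDA (-2.04).

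Some genes jumped between libraries of 1 group. With at least 10 FPKM in the highest library and over 20 times the lowest, there were 10 such genes in sgControl and 8 in sgPLOD2. The epithelial marker CLDN4 had 53.3, 0.101 and 50.9 FPKM in sgControl and 0.535, 0.388 and 0.489 FPKM in sgPLOD2. MYC had 9.98, 0.776 and 0.742 FPKM in sgControl and 12.5, 1.01 and 24.4 FPKM in sgPLOD2, and IER2 had 0.454, 23.2 and 0.535 FPKM in sgPLOD2.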
